A study of Mus musculus with 10 samples.

How the data were processed

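RNA from sorted lung endothelial cells of 10 samples was analysed, 1 array each. Per the labels' protocols, RNA was isolated with a PicoPure kit, checked on a Bioanalyzer, reverse transcribed and amplified by NuGEN single primer isothermal amplification, then labelled with biotin for Illumina beadchips. The scanner and its software, the tamoxifen schedule, the sorting markers, and whether a sample was 1 animal or a pool are not given in the sources used here, so p-values measure the spread between these samples. Deleted samples carried floxed alleles with Cdh5-CreERT2 and controls lacked Cre, per the labels.

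The authors deposited a table of mean bead intensity per probe and array, named as not normalized, with a detection p-value per probe and array, per the file headers. They also deposited a table of normalized intensity on a linear scale, whose array means all lay between 139.8 and 140.7 and medians between 101.8 and 105.2; its method is not given in the sources used here. Each array's deposited normalized values followed its own intensities in rank (Spearman's rho at least 0.9996, against at most 0.877 for any other array). No pair of arrays held the same values throughout. The deposited p-values reached 3.20e-87, so they are not ranks among negative control probes, and how they were computed is not given in the sources used here. The main background correction infers negative controls from these p-values, as if they were such ranks. An alternative that does not use them was therefore added after seeing the data.

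Computation used R 4.3.3 with limma 3.58.1; figures used Python 3.11.15 and matplotlib 3.10.9. Intensities were background-corrected and quantile-normalized with neqc (offset 16) and taken to log2. Probes with a detection p below 0.05 on at least 2 arrays were kept, 30017 of 46237. A probe's gene came from the platform annotation: 35784 probes had 1 symbol, none several and 10453 none. Symbols were updated through the Entrez identifier (28620 probes) or the accession (2637) against RefSeq names of the GRCm38.p6 assembly and otherwise kept as given (4527); 937 changed. Among probes past the filter 24246 had a symbol; the brightest probe represented each of 16144 genes, 5321 of which had several. A probe not detected on any array of a group counted as not well above background there, and its fold is a lower bound against the lowest detected signal. That bound holds for the main processing only and makes no allowance for sampling error.

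A linear model of the 4 group means was fitted to all 10 arrays with limma, so that the groups shared an estimate of spread, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The Evi-iECKO arrays had the lowest correlation of any pair of arrays (Pearson's r of 0.931 across genes). The shared spread may therefore understate theirs in the Evi/Wls and joint p-values. The comparisons were each deletion within its line, their mean, their difference, and the wild-type arms. The lists of genes, the tests of these comparisons, the rule for named genes and the alternatives, other than those said to be added later, were fixed before the data were examined. The plan named list tests only for each deletion and their mean. List tests for the difference and the wild-type arms went beyond it. Of 741 genes on 40 lists, covering Wnt signalling, endothelial subtypes, cell cycle, stress responses and other lung cells, 597 were measured. Lists were tested with camera (preset correlation 0.01), adjusted over the lists within a comparison; camera with an estimated correlation and fry were run beside it, and neither called any list in any comparison at an adjusted p below 0.05. Co-regulated genes were those with an unadjusted p below 0.05 and the same direction in each line; the lines have separate controls. The named genes were Rspo3, Wls and Cdh5; for each deletion and the joint effect, up to 10 genes per direction that passed, made up to 5 by smallest p where fewer did; 10 co-regulated genes per direction; 5 per direction for the difference and the wild-type arms where they passed; and up to 4 members of a list. Symbols that only number a clone or locus were passed over; other genes of a list were named after their values were seen.

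The scripts were tested on simulated arrays with the spread of the real ones. In them 100 genes were altered 2-fold and 100 were altered 4-fold at once, and genes varied independently. For the joint effect 75% of genes altered 2-fold and 99% of those altered 4-fold were recovered. So many altered genes ease the adjustment over all genes, so these shares do not give the recovery where few genes are altered. Alternatives comprised other background corrections and normalizations, the authors' normalized values, other filters, array weights, a trended robust variance prior, the mean of all probes of a gene, a replicate block, fits to the arrays of 1 line, other thresholds, sex by Xist as a factor (added after seeing the data) and leaving out each array. Xist was high on 1 array of each group. All 100 regroupings of the arrays within lines were also fitted. In them camera with its preset correlation called a median of 2 lists for the joint effect, so a call alone does not exclude chance. Lists called were not counted in this way for the other comparisons. The 5771 probes past the filter without a symbol were tested apart and none passed in any comparison.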

Results

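Gene expression was measured on 10 Illumina mouse beadchip arrays hybridised with RNA from lung endothelial cells, the cells that line the blood vessels, sorted by flow cytometry from C57/Bl6 mice at postnatal day 6. In 1 mouse line the R-spondin gene Rspo3 could be deleted and in the other the gene Evi/Wls, each through an inducible Cre recombinase driven by the endothelial Cdh5 promoter. Rspo3 encodes a secreted protein that amplifies Wnt signals, and Wls (also called Evi) encodes the membrane protein that carries Wnt ligands to the cell surface for secretion. The arrays comprised 3 from Rspo3-deleted mice (Rspo3-iECKO), 2 from their Cre-negative controls (Rspo3-WT), 2 from Evi/Wls-deleted mice (Evi-iECKO) and 3 from theirs (Evi-WT). Each array carried 46237 probes, of which 46.5% to 51.3% were detected above background, and the median intensity per array ranged from 89.6 to 110. After filtering, 16144 genes were tested. The number of arrays limited the precision, and the median standard error of a fold change within a line was 0.22 on the log2 scale. Values below are log2 differences of normalized intensities unless a fold is named.

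The deleted genes were examined first. Wls was 2.14-fold lower in Evi-iECKO than in Evi-WT (log2 fold change -1.10, SE 0.27). Under alternatives other than leaving out arrays, the log2 fold change of Wls ranged from -1.26 to -0.45. Its normalized level was 4.76 ± 0.13 (SD, n = 2) in Evi-iECKO and 5.86 ± 0.30 (SD, n = 3) in Evi-WT, with both deleted arrays below all 3 control arrays. The limma p-value was 0.0014 before adjustment and 0.357 after Benjamini-Hochberg adjustment over all genes, so Wls did not pass over all genes; it did pass when adjusted over the list alone, among the 8 measured genes for Wnt ligands and their secretion. A further Wls probe gave -1.43 (SE 0.28, unadjusted p = 2.06e-04), and the third was not well above background on any array. In the Rspo3 line Wls differed by -0.18 (SE 0.27), but Rspo3-iECKO replicate 1, at 4.96, lay below the other arrays of that line, which read 5.55 to 5.85. On all 5 arrays of the Rspo3 line both Rspo3 probes were not well above background, so the arrays do not check the deletion of Rspo3. Where the probes lie relative to the deleted exons is not given in the sources used here. Cdh5, the VE-cadherin gene whose promoter drives Cre and which marks endothelium, was bright in every group and differed by 0.03 (SE 0.25) in the Rspo3 line and -0.05 (SE 0.25) in the Evi/Wls line.

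**Figure D1:**
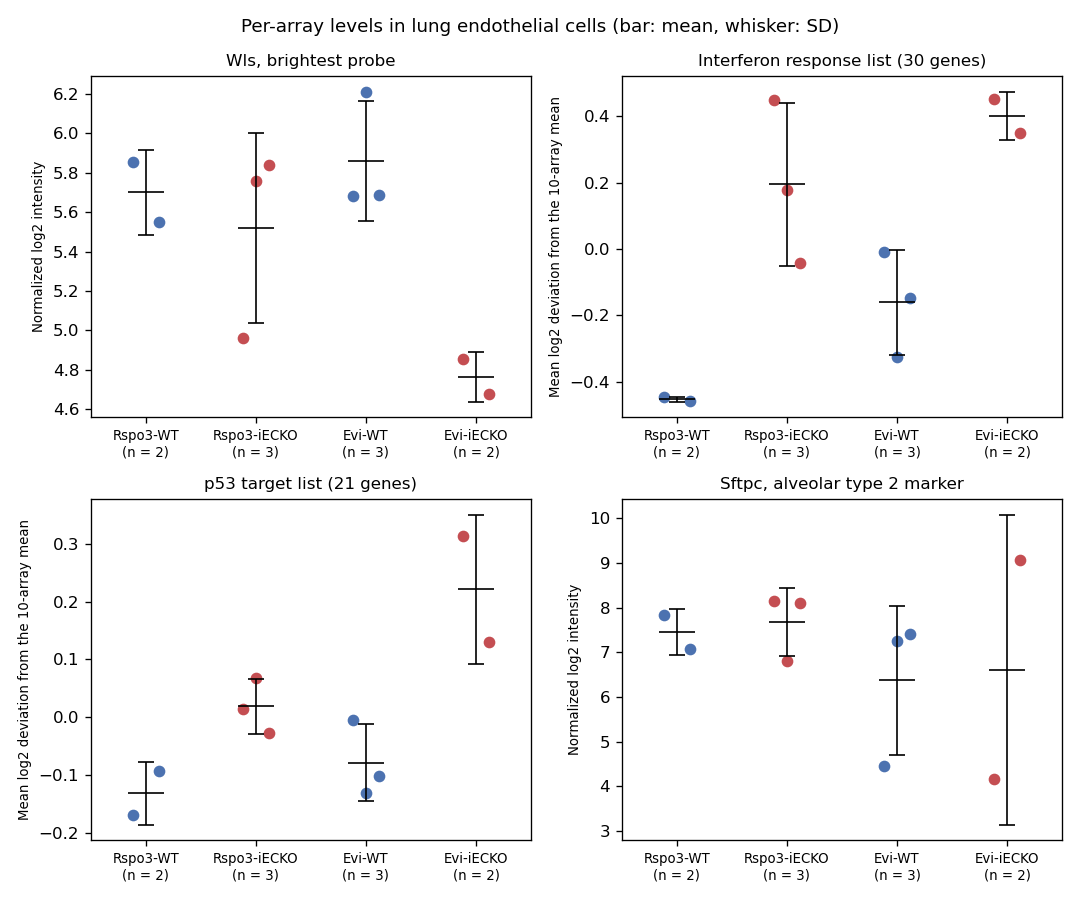
Levels on each of the 10 arrays by group, with wild-type arrays in blue and deleted arrays in red; the bar is the group mean and the whisker the SD. The panels show the normalized log2 intensity of Wls, the mean log2 deviation of the 30 interferon response genes and of the 21 p53 targets from the mean of all arrays, and the normalized log2 intensity of Sftpc. Both Evi-iECKO arrays lie below the Evi-WT arrays for Wls, the interferon score runs from -0.46 in Rspo3-WT to 0.45 in Evi-iECKO, and the Evi-iECKO arrays read 4.16 and 9.07 for Sftpc.

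Loss of Rspo3 was accompanied by higher levels of interferon-induced genes. Of 30 measured interferon response genes, 29 were higher in Rspo3-iECKO than in Rspo3-WT, with a median of 0.58. Among them 10 passed when adjusted over the list alone, and none passed over all genes. Oasl2, a member of the oligoadenylate synthetase-like family, was 2.54-fold higher (log2 1.34, SE 0.25), and Usp18, which dampens interferon receptor signalling, was 2.85-fold higher. Sp100, a component of nuclear bodies that interferon induces, was 2.63-fold higher and stood outside the list. The list was called higher by camera with its preset correlation (adjusted p = 1.00e-21), with an adjusted p = 0.114 with an estimated correlation. Across all 10 ways of dividing these 5 arrays the real grouping gave the highest list median, an exact one-sided p of 0.1, which is the smallest that this design allows. No other list of the 40 was called, and the medians of the other 39 lay between -0.19 for airway epithelium and 0.16 for S-phase genes. Targets of the tumour suppressor p53 were called with median scaling (adjusted p = 0.0122), the authors' normalized values (0.0415), the mean of all probes (0.042) or without Rspo3-iECKO replicate 3 (0.046), against an adjusted p of 0.127 with all arrays.

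No single gene passed the threshold for the Rspo3 deletion. The smallest limma adjusted p was 0.457, and 379 genes were higher and 324 lower at an unadjusted p below 0.05, where 807 in total are expected by chance among independent genes. The genes of smallest p, none of which passed, included Srpr (at least 2.37-fold higher, Rspo3-WT being not well above background), Cul4a, a scaffold of ubiquitin ligases (2.04-fold higher), and Gng11, a G-protein gamma subunit (at least 1.73-fold higher). On the lower side were Pgap2, which remodels GPI anchors (3.03-fold lower), Noxo1, an organiser subunit of NADPH oxidase 1 (2.33-fold), Cox14 (2.13-fold), Ephb1, an ephrin receptor (1.88-fold), and Sdf2l1, an endoplasmic reticulum protein (1.80-fold). In data simulated with the spread of these arrays, 53% of genes altered 2-fold and 98% of those altered 4-fold were recovered for this comparison. Many genes were altered there at once, which eases the adjustment, so these shares do not carry over to the real arrays.

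Loss of Evi/Wls likewise came with higher interferon response genes. In Evi-iECKO 28 of the 30 measured genes were higher, with a median of 0.46, and 7 passed when adjusted over the list alone. Ifit3, an interferon-induced tetratricopeptide protein, was 4.74-fold higher (log2 2.24, SE 0.40), Usp18 was 3.47-fold higher and the chemokine gene Cxcl10 differed by 1.60. Outside the list, Nlrc5, the transactivator of MHC class I genes, was 3.21-fold higher. The list was called higher by camera (adjusted p = 8.35e-10), with an adjusted p = 0.263 with an estimated correlation and an exact one-sided p of 0.1 for the list median over the 10 divisions of these arrays.

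A further 5 lists were called between Evi-iECKO and Evi-WT by camera with its preset correlation. At that setting regroupings of the arrays within lines also called lists, a median of 2 for the joint effect. The p53 targets were higher (median 0.20, 16 of 21 positive, 3 adjusted over the list alone, camera adjusted p = 0.0037; adjusted p = 0.263 with an estimated correlation), and leaving out Evi-iECKO replicate 1 or Evi-WT replicate 3 ended that call, with adjusted p-values of 0.267 and 0.0709. The general capillary list was lower (median -0.11, 12 of 15 negative, 2 adjusted over the list alone, adjusted p = 0.0181; adjusted p = 0.263 with an estimated correlation), a call that ended without the same arrays (0.267 and 0.0838). Hypoxia and glycolysis genes were lower (median -0.17, adjusted p = 0.0284; adjusted p = 0.263 with an estimated correlation), with none passing when adjusted over the list alone; Egln3, an oxygen-sensing prolyl hydroxylase, read -0.70 and Ankrd37 -0.85. With arrays left out in turn Ankrd37 ranged from -1.27 to -0.43. The hypoxia call ended without Evi-WT replicate 1 (median -0.11, camera adjusted p = 0.151). It also ended without Evi-iECKO replicates 1 or 2 (medians -0.20 and -0.23), each leaving 1 array in that group. No filter and a stricter filter on dim probes ended it too (adjusted p = 0.0917 and 0.065). S-phase genes were higher (median 0.22, camera adjusted p = 0.028, or 0.784 with an estimated correlation), again with none passing when adjusted over the list alone. That call ended without Evi-WT replicate 2 (median 0.22, adjusted p = 0.0658) or replicate 3 (median 0.05, adjusted p = 0.683). It also ended without Evi-iECKO replicates 1 or 2 (medians 0.21 and 0.15), each leaving 1 array in that group. No filter (adjusted p = 0.0697), array weights (0.0543) and the mean of all probes (0.129) ended it as well. Markers of alveolar type 2 cells, the epithelial cells that make surfactant, were all 12 higher (median 0.75, adjusted p = 0.0024; adjusted p = 0.784 with an estimated correlation), with none passing when adjusted over the list alone. The Evi-iECKO arrays lay far apart, with a list score of 1.88 for replicate 2 and -1.03 for replicate 1; without replicate 2 the median was -0.52 (adjusted p = 0.0317, called lower) and without replicate 1 it was 2.60. Without Evi-WT replicate 1 the list was not called (adjusted p = 0.0605). Fibroblast markers were not called (median 0.18, adjusted p = 0.0538), nor were genes for Wnt ligands and their secretion (median -0.15, adjusted p = 0.363). The 34 lists not called had medians from -0.22 for sex-linked genes to 0.20 for venous endothelium.

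No single gene passed for the Evi/Wls deletion in limma, the smallest adjusted p being 0.21; 722 genes were higher and 568 lower at an unadjusted p below 0.05. Besides Ifit3, Nlrc5 and Usp18, the genes of smallest p on the higher side were Plxna2, a semaphorin receptor (2.13-fold), and Gstt4, a glutathione transferase (at least 1.78-fold, Evi-WT being not well above background). On the lower side were Glce, an enzyme that modifies heparan sulphate (2.72-fold), Ring1, a Polycomb ubiquitin ligase (at least 1.99-fold, Evi-iECKO being not well above background), Mpdz, a scaffold of cell junctions (2.10-fold), Man1b (2.06-fold) and Crybb3 (1.87-fold). Without Evi-iECKO replicate 1, that group was left with replicate 2 alone. The surfactant genes Sftpa1 and Sftpb then read 2.68 and 2.51, and Cdh1, E-cadherin of epithelia, 1.36. Without Evi-iECKO replicate 2, that group was left with replicate 1 alone. Cxcl10 then read 2.36, and Gm4951 was higher, Evi-WT being not well above background. Leaving out Rspo3-iECKO replicate 3, which enters the shared spread, gave 1 gene past the threshold, Ifit3 (adjusted p = 0.0346). Cdh1 and Gm4951 were named after their values were seen. The simulated recovery for this comparison was 46% at 2-fold and 97% at 4-fold, with the same limit as for Rspo3. On the real arrays Ifit3 did not pass with all arrays at a log2 fold change of 2.24.

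The study asked which endothelial genes respond to both deletions, and the mean of the deletion effects within each line was tested for this. Interferon response genes made up the clearest shared change. Of the 30 measured, 28 were higher, 27 of them in each line separately, with a joint median of 0.55. In the joint effect 23 had an unadjusted p below 0.05 and 22 passed when adjusted over the list alone. An unadjusted p below 0.05 in each line separately was reached by 6. A joint value can rest mostly on 1 line: Cxcl10 read 0.24 in the Rspo3 line and 1.60 in the Evi/Wls line, and Mx2 0.77 and 0.12. The largest joint changes were those of Ifit3 (3.23-fold, log2 1.69, SE 0.29), Usp18 (3.14-fold, log2 1.65, SE 0.26), Oasl2 (2.38-fold, log2 1.25, SE 0.17) and, by p, Stat2, the transcription factor of type I interferon signalling (1.86-fold, log2 0.90, SE 0.16). The 8 members that did not pass were Oas3 (0.02), Irf1 (0.18), Oasl1 (0.20), Psmb8 (0.28), Ifih1 (0.30), Rsad2 (0.57), and Bst2 and Irf7, which were not well above background in Rspo3-WT and Evi-iECKO. The list's mean score per array was 0.19 ± 0.25 (SD, n = 3) in Rspo3-iECKO against -0.45 ± 0.01 (n = 2) in Rspo3-WT, and 0.40 ± 0.07 (n = 2) in Evi-iECKO against -0.16 ± 0.16 (n = 3) in Evi-WT. Camera called the list higher (adjusted p = 5.08e-26), with an adjusted p = 0.0723 with an estimated correlation.

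**Figure D2:**
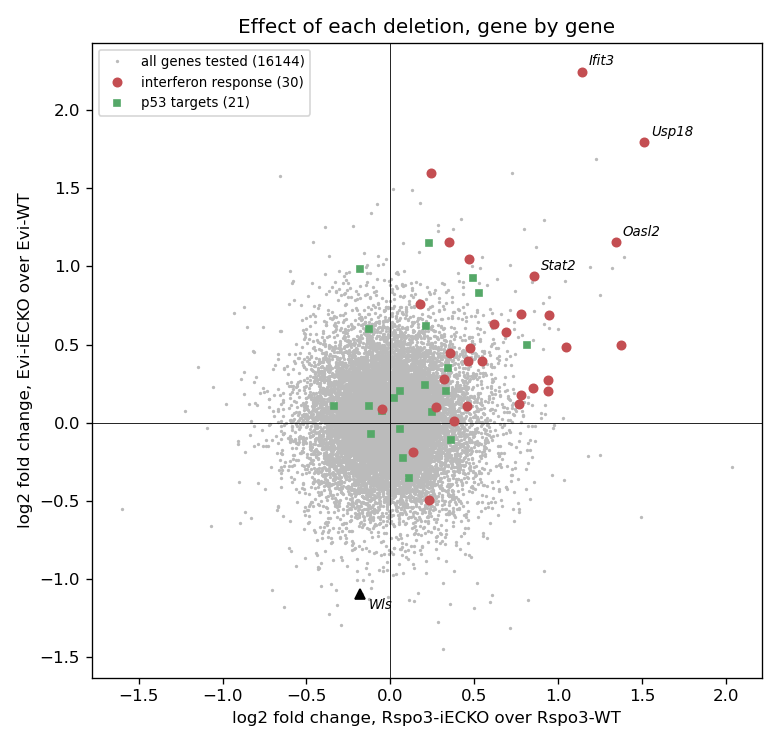
Log2 fold change of each of the 16144 genes tested on deletion of Rspo3 (horizontal axis) and of Evi/Wls (vertical axis); grey points are all genes, red circles the 30 interferon response genes, green squares the 21 p53 targets and the black triangle Wls. The interferon response genes lie mostly in the upper right quadrant, with 27 of 30 higher in both lines, whereas the correlation over all genes is 0.03.

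The p53 targets were also called higher in the joint effect, with 16 of 21 positive and a median of 0.16 (camera adjusted p = 2.54e-04; adjusted p = 0.104 with an estimated correlation). Adjusted over the list alone, 5 passed. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was 1.64-fold higher (log2 0.71, SE 0.16), Ccng1 1.57-fold (SE 0.13), Phlda3, an inhibitor of Akt, 1.61-fold, and Rps27l 1.33-fold; Sesn2, a stress-responsive inhibitor of mTORC1, was the fifth at 0.68. In contrast Mdm2 (-0.08), Fas (0.01) and Plk2 (0.01) showed no difference beyond their standard errors. In the Rspo3 line alone the list was not called (median 0.11, camera adjusted p = 0.127). Without Evi-iECKO replicate 1, which left 1 array in that group, the joint call ended though the median was 0.19.

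Among the endothelial lists, general capillary genes were called lower (joint median -0.11, 13 of 15 negative, none passing when adjusted over the list alone; adjusted p = 0.0114). The adjusted p = 0.2 with an estimated correlation. In the Rspo3 line alone the median was 0.0030 with 8 of 15 positive (adjusted p = 0.581), and in the Evi/Wls line it was -0.11. Hilpda, a lipid droplet protein induced by hypoxia, read -0.59 (SE 0.16), the axon guidance ligand gene Sema3c -0.48 and the angiopoietin receptor gene Tek -0.27. The call ended with median scaling of the arrays (median 0.0023, adjusted p = 0.126) and without Rspo3-WT replicate 1 or Evi-iECKO replicate 1 (adjusted p = 0.107 and 0.112). S-phase genes were called higher (median 0.18, 17 of 23 positive, adjusted p = 0.0114; adjusted p = 0.758 with an estimated correlation), with Chaf1b, a chromatin assembly factor, 1.60-fold higher and passing when adjusted over the list alone. In the Rspo3 line alone the S-phase median was 0.16 with 12 of 23 positive (adjusted p = 0.49). The joint S-phase call ended without Evi-WT replicate 3 (median 0.12, camera adjusted p = 0.277) and with the mean of all probes (median 0.10, adjusted p = 0.0767). It also ended in fits that left 1 array in a group. The median was 0.06 without Rspo3-WT replicate 2, and 0.17 and 0.16 without Evi-iECKO replicates 1 and 2. Pan-endothelial genes (median -0.02), junction genes (-0.02), aerocyte genes (0.06) and arterial (-0.05), venous (0.12) and lymphatic (0.03) genes were not called. The 34 lists not called in the joint effect had medians from -0.16 for platelet markers to 0.18 for alveolar type 1 markers.

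Canonical Wnt/beta-catenin targets were not called in the joint effect: 9 of 18 were higher, none passed when adjusted over the list alone, and the median was 0.0020 while camera pointed lower (adjusted p = 0.768). The joint value averages lines that pointed apart. The mean list score was -0.04 (-0.06 to -0.0067) in Rspo3-iECKO and 0.05 (0.02 to 0.08) in Rspo3-WT. In the Evi/Wls line it was 0.03 (0.02 to 0.04) in Evi-iECKO and -0.01 (-0.04 to 0.02) in Evi-WT. For the Rspo3 deletion alone the list was not called (median -0.06, camera adjusted p = 0.581). The members of smallest p in the joint effect were Prickle1 (-0.29), the Wnt inhibitor Wif1, Cd44 (-0.36) and Myc, with adjusted p-values of 0.823 to 0.88 in limma over all genes. Myc was not well above background in either wild-type group, nor Wif1 in Evi-iECKO. Wnt and R-spondin receptors and modulators were not called either (median -0.01, adjusted p = 0.995), nor were genes of the calcineurin-NFAT pathway, a branch of calcium-dependent signalling (median 0.02, adjusted p = 0.557). Of the latter Rcan3 read 0.43, Tnfaip3 0.29 and Icam1 0.28, none passing when adjusted over the list alone.

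Markers of other lung cells were read beside these. Fibroblast markers were called higher in the joint effect (median 0.14, 13 of 14 positive, adjusted p = 0.0114; adjusted p = 0.195 with an estimated correlation). Only Dcn, decorin, passed when adjusted over the list alone, and as it was not well above background in Rspo3-WT and Evi-iECKO its joint value does not support the call. Col3a1 read 0.32 and Gpc3 0.29. Their call ended without Evi-iECKO replicate 2 (median 0.03, adjusted p = 0.312), Rspo3-WT replicate 2 (0.0943) or Evi-WT replicate 2 (0.0511), and with median scaling (0.0796), the authors' values (0.0821), a stricter filter (0.114) or the mean of all probes (0.0509). In the Rspo3 line alone the fibroblast median was 0.12 (adjusted p = 0.382). Alveolar type 2 markers were called higher too (median 0.39, adjusted p = 0.0144; adjusted p = 0.758 with an estimated correlation), with a median of 0.0052 and 6 of 12 positive in the Rspo3 line alone (adjusted p = 0.988), and stood at -0.27 without Evi-iECKO replicate 2. That call ended without Rspo3-WT replicate 2 (0.28) or Evi-WT replicate 1 (0.149) and with no filter on dim probes (0.0725). The joint medians of macrophage and monocyte markers (0.04), neutrophil markers (0.08), lymphocyte markers (0.0028), pericyte and smooth muscle markers (-0.02), mesothelial markers (-0.02), erythroid markers (-0.12) and platelet markers (-0.16) were not called.

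No single gene passed for the joint effect in limma at an adjusted p below 0.05. The smallest was 0.116, for Oasl2 and Sp100; 519 genes were higher and 420 lower at an unadjusted p below 0.05. The 5 higher genes of smallest p were Oasl2, Sp100 (2.34-fold), Usp18, Nlrc5 (2.74-fold) and Ifit3. On the lower side they were Pgap2 (2.10-fold), Man1b (1.66-fold), Smcx, an older symbol of the X-linked histone demethylase Kdm5c (1.85-fold), Mpdz (1.62-fold) and Cdon, a co-receptor of hedgehog signalling for which Evi-iECKO was not well above background. With a trended robust variance prior 6 genes passed, namely Oasl2, Sp100, Usp18, Nlrc5, Ifit3 and Rnf213, a ubiquitin ligase. Without Evi-iECKO replicate 2 the number was also 6, namely Trim30a, Cxcl10, Chek1, Nlrc5, Rnf213 and Arid3b. Without Evi-iECKO replicate 1 it was 4, namely Sftpb, Ces1d, Cd74 and Spint1. Without Evi-WT replicate 1 it was 3 (Batf2, Gvin1 and Oasl2), and without Rspo3-iECKO replicates 1 or 3 it was 1 (Usp18 and Ifit3, respectively). The fits without an Evi-iECKO array left 1 array in that group, so their counts rest on that array. Chek1, Arid3b, Ces1d, Cd74, Spint1, Batf2 and Gvin1 were named after their values were seen.

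Genes that moved the same way in each line at an unadjusted p below 0.05 numbered 45 higher and 21 lower, where independent lists would share 16.9 and 11.4. Genes moving in opposite directions numbered 27 and 20, against 13.3 and 14.5 expected. None of the 66 passed after adjustment in both lines. The 10 higher genes with the smallest of the larger p-values were Oasl2, Sp100, Usp18, Stat2, Nlrc5, Trim30a (2.13-fold in the joint effect), Rnf213 (1.83-fold), Gbp9, a guanylate-binding protein (1.60-fold), Stx2, a syntaxin (at least 1.84-fold in the Rspo3 line, Rspo3-WT being not well above background), and Meis2, a homeobox transcription factor (1.54-fold). Members of the interferon list made up 6 of the 45. The 10 lower genes were Cdon, Smcx, Arhgap42 (1.53-fold), Fam120c (1.44-fold), Usp46 (1.52-fold), Aqr (1.70-fold), Snurf (1.65-fold), Pold4, a subunit of DNA polymerase delta (1.46-fold), Gpc4, a glypican, and Miga1 (1.53-fold). In the Evi/Wls line Cdon was at least 1.39-fold and Gpc4 at least 1.31-fold lower, Evi-iECKO being not well above background. Without Evi-iECKO replicate 2 the total was 106. Over all genes the deletion effects were almost unrelated, with Pearson's r of 0.03 and Spearman's rho of 0.0041 across genes, which are not independent replicates.

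Whether the deletions differed was tested directly as the Rspo3 effect minus the Evi/Wls effect. No gene passed in limma (smallest adjusted p = 0.146; 429 genes higher and 550 lower at an unadjusted p below 0.05), and no list was called. Interferon response genes had a median difference of 0.13 (camera adjusted p = 0.547). The list nearest to the threshold was hypoxia and glycolysis (median difference 0.16, adjusted p = 0.0734). The alveolar type 2 list had the lowest median, -0.94 (adjusted p = 0.0734), with the Evi-iECKO arrays far apart as described. Without Evi-iECKO replicate 1, which left 1 array in that group, Sftpb read -2.44 and Glce 2.30.

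The wild-type arms of the lines served as background to the deletions, and 6 genes differed between them in limma (732 higher and 690 lower in Rspo3-WT at an unadjusted p below 0.05). Higher in Rspo3-WT were the histone genes H2bc15 (3.20-fold, adjusted p = 0.0384) and H2ac13 (2.56-fold, adjusted p = 0.0384), Pfn1, the actin-binding protein profilin 1 (2.62-fold, adjusted p = 0.0384), and Psmd2, a proteasome subunit (at least 2.50-fold, adjusted p = 0.0384, Evi-WT being not well above background). Lower were Polg2, the accessory subunit of mitochondrial DNA polymerase (3.88-fold, adjusted p = 0.0366), and Neurl (4.36-fold, adjusted p = 0.0491). Leaving out any 1 of Rspo3-iECKO replicates 1 or 3, Rspo3-WT replicates 1 or 2, or Evi-WT replicates 2 or 3 left 0 genes in limma, and leaving out Rspo3-iECKO replicate 2 left 2, Polg2 and Neurl. The share of probes detected also separated the lines, at 49.8% to 51.3% on arrays of the Rspo3 line and 46.5% to 48.6% on those of the Evi/Wls line.

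Interferon response genes were called lower in Rspo3-WT than in Evi-WT (median -0.26, 25 of 30 negative, 2 adjusted over the list alone, adjusted p = 0.0076; adjusted p = 0.748 with an estimated correlation), with Rtp4 2.20-fold and Gbp3 1.92-fold lower. That call was lost without Evi-WT replicate 1, at an adjusted p of 0.0605. Pericyte and smooth muscle markers were called higher (median 0.27, 1 adjusted over the list alone, adjusted p = 0.0084; adjusted p = 0.729 with an estimated correlation), led by the myosin light chain gene Myl9 (2.32-fold). S-phase genes were called higher (median 0.28, none adjusted over the list alone, adjusted p = 0.0172; adjusted p = 0.748 with an estimated correlation), and aerocyte genes too (median 0.19, 1 adjusted over the list alone, adjusted p = 0.0417; adjusted p = 0.748 with an estimated correlation), the latter led by Tbx2 (2.06-fold). Immediate-early and heat-shock genes, which cell isolation can induce, were called lower (median -0.24, none adjusted over the list alone, adjusted p = 0.0264; adjusted p = 0.729 with an estimated correlation), with Hspa1a 3.77-fold and Fos 1.69-fold lower and Hspa8 1.65-fold higher. Without Rspo3-WT replicate 1, which left 1 array in that group, the pericyte, S-phase and immediate-early calls ended (medians 0.14, 0.12 and -0.22). The immediate-early call also ended without Rspo3-WT replicate 2 (median -0.26, again with 1 array left). It ended too without Evi-WT replicate 1 (median -0.18, camera adjusted p = 0.186) and with median scaling (median -0.06, adjusted p = 0.274). The S-phase call ended without Evi-WT replicate 3 (median 0.10, adjusted p = 0.48). The aerocyte call ended without Evi-WT replicate 3, where the median was -0.0036 (camera adjusted p = 0.607), so that array carried the shift. It also ended without Rspo3-WT replicate 2 (median 0.11) or Evi-iECKO replicate 1 (median 0.19), each leaving 1 array in its group. Array weights (adjusted p = 0.0776) or sex as a factor (0.0734) ended it too, the last chosen after seeing the data.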

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

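The interferon list was called higher in the Rspo3, Evi/Wls and joint comparisons under every other normalization, filter, fit and left-out array tried (22 of 22, 22 of 22 and 21 of 21), with joint medians of 0.25 to 0.65. It was not called with an estimated correlation (medians 0.58, 0.46 and 0.55; adjusted p = 0.114, 0.263 and 0.0723) or with fry (0.199, 0.123 and 0.0534), which called 0 lists in each of these comparisons. No gene passed for the Rspo3 deletion under any alternative run. Co-regulated genes numbered 0 when both adjusted p-values had to pass, 15 at an unadjusted p below 0.01, 30 with at least 1.5-fold in both and 115 with no filter, which tests 21946 genes. Genes between the wild-type arms numbered 11 with quantile normalization alone, 45 with median scaling, 31 with a trended robust prior, and 0 with no filter, the mean of all probes or sex as a factor. Median scaling shifted the median of all genes by 0.11 in the Rspo3 line, gave a correlation of the deletion effects of -0.0493 and called 4 lists for Rspo3. The authors' values and the mean of all probes each called 2 there. The joint effect had 6 genes with a trended robust prior and 1 (Oasl2) with sex as a factor, an alternative chosen after seeing the data, as was normexp with offset 50. The cause of these changes was not tested. In the replicate block, 1 gene (Ifit3) passed for Evi/Wls and 1 (Ifit3) for the joint effect, and 2 lists were called for Rspo3, interferon response and p53 targets (median 0.13, adjusted p = 0.0459). It ended the S-phase calls for the joint effect (median 0.09, adjusted p = 0.213) and Evi/Wls (0.05, 0.547) and the general capillary call for Evi/Wls (-0.13, 0.0873). Only 2 numbers are shared per line. Same-numbered arrays deviated from their group means with correlations of -0.0154 and 2.04e-04 in the Rspo3 line and 0.127 and -0.122 in the Evi/Wls line. In an arm of 2 arrays the deviations mirror each other by construction, so these values cannot settle whether the numbers pair samples. The numbers were not taken to pair them. With each array left out in turn, genes passing ranged from 0 to 23 for Evi/Wls (23 without Evi-iECKO replicate 1, 2 without Evi-iECKO replicate 2 and 1 without Rspo3-iECKO replicate 3), 0 to 6 for the joint effect, 0 to 6 for the difference and 0 to 9 for the wild-type arms. Co-regulated genes ranged from 50 to 106, highest without Evi-iECKO replicate 2. The correlation ranged from -0.0492 without Evi-iECKO replicate 1 to 0.0886 without replicate 2. Lists called ranged from 1 to 3 for Rspo3 (2 without Rspo3-iECKO replicate 3, 3 without either Rspo3-WT array), 3 to 7 for Evi/Wls (3 without Evi-WT replicate 3) and 3 to 7 for the joint effect (3 without Rspo3-WT replicate 2). Where this left 1 array in an arm, that array is assumed to vary like the other groups. Camera's direction for Wnt and R-spondin receptors (joint median -0.0108) turned with quantile normalization alone and normexp, where the median also changed sign (0.0058 and 0.0072), and in the replicate block, with a trended robust prior and with the mean of all probes, where it did not (-0.0328, -0.0108 and -0.0088). With arrays left out that median was -0.12 to 0.0333. With arrays left out Cdh5 ranged from -0.0946 to 0.16 in the Rspo3 line (0.02 to 0.29 under the other alternatives) and -0.48 to 0.38 in the Evi/Wls line. In the Evi/Wls line, leaving out arrays moved the alveolar type 2 list from -0.52 to 2.60 (joint -0.27 to 1.26), Sftpb from -0.20 to 2.51, Etv5 from -0.0173 to 1.44, Chil1 from -0.19 to 2.37 and Aldoa from -1.05 to 0.12; the negative values of the list and of Sftpb, Etv5 and Chil1 came without Evi-iECKO replicate 2. Apart from the interferon list in the Rspo3, Evi/Wls and joint comparisons, 52 list results under an alternative were weaker and 5 stronger, 353 stayed on the same side and 12 turned. Among named genes 67 were weaker and 19 stronger, 3069 stayed on the same side and 8 turned. A beadchip block was not run, as no chip is named in the sources used here, and the replicate block cannot give the wild-type comparison. Fits to 1 line gave only single-line values. Signal over background limits Rspo3, Srpr, Gng11, Gstt4, Ring1, Psmd2, Stx2, Cdon, Gpc4, Dcn, Myc, Wif1, Bst2, Irf7, Chek1, Spint1, Gbp5 and Gm4951, whose probes were at background in a group.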

Other observations

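The tests on leukocytes, Cre, the alveolar type 2 list, S-phase genes, the strongest of all lists, the higher co-regulated genes alone and the regroupings for the medians of single lists were chosen after the results they bear on were seen. For the interferon list this was after its median but before the regroupings were run, and the other regroupings of the arrays were set before their results. Of the 45 genes higher in each line at an unadjusted p below 0.05, 39 lay outside the interferon list, and none passed after adjustment. Genes picked from these 39 after their values were seen, with no test of enrichment, were the immunity-related GTPases Igtp (0.84 in the Rspo3 line and 0.90 in the Evi/Wls line) and Irgm2 (1.25 and 0.82), the guanylate-binding proteins Gbp5 (at least 1.69-fold, Rspo3-WT being not well above background, and 1.24) and Gbp10 (0.87 and 1.12), Gvin1 (1.32 and 0.99), Eif2ak2, the kinase PKR (0.74 and 0.64), and Parp14 (0.86 and 0.71). Hgf, hepatocyte growth factor, was among the lower genes (-0.45 and -0.68) and likewise named after its values were seen. Replication-dependent histone genes, a set of 56 put together after the wild-type comparison was seen, were higher in Rspo3-WT than in Evi-WT in 48 cases, with a median of 0.76, and 2 passed. The deletion effects have these same wild-type arrays as controls, so opposite signs in them can arise with no effect of deletion. The genes were lower in 50 of 56 cases on Rspo3 deletion (median -0.29; p = 0.13 with an estimated correlation) and higher in 48 on Evi/Wls deletion (median 0.29; p = 0.185 with an estimated correlation), none passing. Leaving out 1 array moved the Rspo3 median to -0.17 (without Rspo3-WT replicate 1) or -0.43 (without Rspo3-WT replicate 2) and the Evi/Wls median to 0.17 (without Evi-iECKO replicate 2), 0.50 (without Evi-iECKO replicate 1), 0.48 (without Evi-WT replicate 1) or 0.19 (without Evi-WT replicate 3). With median scaling the Rspo3 median was -0.01 with 26 of 56 positive, where all genes shifted by 0.11.

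For the joint effect, whether chance can be excluded depended on the result. For the interferon median chance in how arrays fell into groups can be excluded only at the smallest share that 100 groupings within lines allow (1 of 100; real 0.55, highest other 0.47). The strongest of all 40 lists in each grouping, by camera with its preset correlation, also had the smallest p in the real one. Its -log10 p was 26.9 (highest other 24.7, median 6.23), so another grouping came close. With an estimated correlation the interferon list had an adjusted p = 0.0723. Medians that fewer than 5 groupings reached were also those of fibroblast markers (1 of 100; 0.142, highest other 0.135), general capillary genes (3; -0.11, lowest other -0.12) and p53 targets (4; 0.16, highest other 0.21), chosen after they were called, unlike those of S-phase genes (9; 0.18, highest other 0.28) and alveolar type 2 markers (32; 0.39, highest other 1.20). Chance cannot be excluded for the 6 lists called, reached by 6 groupings (highest other 9), the 66 co-regulated genes, reached by 6 (highest other 114), and the correlation of 0.03, reached by 31 (highest other 0.16). The 45 higher co-regulated genes alone, a count chosen after it was seen, were reached by 2 (highest other 58). For the count of 0 genes the groupings test nothing, as all 100 must give at least 0 (highest other 5).

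The higher interferon genes in both deleted arms are the pattern most worth following. The values argue against a larger share of leukocytes carried through the sort as the source. Measured macrophage, neutrophil and lymphocyte markers had a joint median of 0.0383, against 0.55 for the interferon genes, and a mean shift of 0.05 (SE 0.05 between arrays). Of these 31 markers 1, Lcn2, is also on another list. Evi-iECKO replicate 2 had the highest scores of the 10 arrays for these cells (0.21, 0.30 and 0.21). Evi-iECKO replicate 1 read 0.02, 0.01 and -0.06, with an interferon score of 0.45 against 0.35 on replicate 2. Marker levels do not show the interferon state of any leukocytes present. Activity of Cre itself, through DNA damage, may contribute, since every deleted array and no control array carried Cre. The p53 targets had a joint median of 0.16 (SE 0.08 over the members) and a mean shift of 0.23 (SE 0.05 between arrays). In the Rspo3 line alone, where the interferon median was 0.58, they were not called (median 0.11, camera adjusted p = 0.127). They thus cannot decide this. Cre and gene loss cannot be told apart here, because no Cre-positive array without a floxed allele was analysed. The loss of Evi/Wls or Rspo3 itself stays open and was not tested apart from Cre.

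The alveolar type 2 shift in Evi-iECKO is consistent with epithelial RNA in amounts that differ between arrays, most on Evi-iECKO replicate 2: its list score was 1.88 against -1.03 to 0.46 on the other arrays, and without it the list median turned to -0.52. Sftpc, a surfactant gene, read 9.07 on that array, 6.81 to 8.14 on those of the Rspo3 line, 7.26 and 7.41 on Evi-WT replicates 2 and 3, and 4.45 and 4.16 on Evi-WT replicate 1 and Evi-iECKO replicate 1. Such RNA was thus not confined to 1 array, and its level was low on both Evi-iECKO replicate 1 and Evi-WT replicate 1. Evi-iECKO replicate 2 also had the highest score of the 10 arrays for mesothelial (0.45), alveolar type 1 (0.24) and fibroblast markers (0.17). The same held for macrophage, neutrophil and lymphocyte markers, but not for airway, pericyte, erythroid or platelet markers. No alveolar type 2 marker is on another list, and the sort for endothelial cells should remove such cells. An effect of losing Evi/Wls on the alveolar type 2 genes stays open and was not tested separately.

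Between the wild-type arms 1422 genes had an unadjusted p below 0.05, against 807 expected among independent genes. A batch or genetic background shared by both arms of a line remains a candidate explanation: the line difference among deleted arrays went with that among wild-type arrays (r = 0.33 across genes), above any of the other regroupings within arms (highest 0.24, median -0.02). Of the 6 genes that passed, Psmd2, Pfn1, Polg2, H2bc15 and H2ac13 also separated the deleted arrays by line, with Pfn1 at 7.86 to 8.09 in Rspo3-iECKO and 6.35 to 6.78 in Evi-iECKO, whereas Neurl did not (5.23 to 6.31 and 5.31 to 6.34). Line and batch cannot be told apart, as no label names a batch. Whether the share of S-phase cells lies behind the histone genes stays open: S-phase genes had a median of 0.28 between the wild-type arms and 0.16 on Rspo3 deletion. Their mean shifts were 0.23 and 0.09, each with an SE of 0.16 between arrays.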
